A study of Mus musculus with 2 samples.

How the data were processed

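RNA was extracted with Trizol from frozen hearts of C57BL/6 mice, per the labels' protocols, and libraries were made from 1 ug of total RNA with the Illumina TruSeq RNA kit, which does not mark strand. One mouse group had transverse aortic constriction (TAC), a surgical narrowing of the aorta that loads the left ventricle with pressure. The other had TAC and dioscin, a plant steroidal saponin, for 4 weeks. The groups were taken from the treatment label of each sample. The treatment protocol, worded alike for both samples, names dioscin after surgery without saying which sample received it, so the TAC library is taken as untreated on the treatment label alone. Each group had 1 library, and the labels do not state whether a library came from 1 heart or from several. A library from hearts without surgery was not analysed here.

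The deposited values are raw counts of reads per gene. Per the submitters' processing notes, the tools were HISAT2 2.1.0 and HTSeq, and the genome build was mm10. The version of HTSeq, the annotation release and the strand setting of the counting were not given in the sources used here. The 5 HTSeq lines that count reads given to no gene were kept out of library sizes and of all comparisons. In the TAC library and the dioscin library respectively, reads in no gene made up 30.04% and 30.03% of all lines counted, reads with several alignments 38.2% and 36.5%, reads in overlapping genes 1.49% and 1.39%, reads of low alignment quality 1.48% in both, and reads not aligned 2.59% and 2.17%.

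Gene names, types and coordinates came from GENCODE release M21 on GRCm38, the build that mm10 names. Of the 55401 gene identifiers, 55141 matched that annotation without the version number and 54349 with it. The 260 without a match held at most 0.007% of a library's gene counts.

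The counts were scaled with the TMM factors of edgeR 4.0.16 in R 4.3.3 and are given as CPM, the count of a gene relative to the scaled size of its library. The log2 ratio of the dioscin library over the TAC library was computed with a pseudocount of 0.5 added to both counts. Each ratio has an exact 95% Clopper-Pearson interval of its counts, which covers counting error and nothing else, since PCR copies were not told apart and differences between mice were not measured. A gene counts as higher or lower in the dioscin library when it reached 1 CPM in at least 1 library, its ratio was at least 2 in either direction, and its interval excluded 1. This is called the size rule below. It is a rule on these 2 libraries and no test of the treatment. A gene at 0 counts in one library has its fold given as at least the limit of its counting interval nearest to 1. A bound against a floor of 3 counts served for such genes in the naming order and, where stated, in list medians. That floor is 0.174 CPM in the TAC library and 0.175 CPM in the dioscin library. The floor bound exceeds the interval limit, for Mybphl 1152-fold against 936.7-fold.

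Lists of genes were written for heart muscle, matrix, signalling, metabolism, cell stress, cell types and library checks. For each of the 38 lists, the median log2 ratio of its members at or above 1 CPM was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to lie apart when its median fell outside the central 95% of the random lists. Members of a list are often regulated together, which the random lists do not copy, so the percentile describes these libraries.

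Genes named in the text followed a rule. It took the 12 genes higher and the 12 lower whose interval bound nearest to 1 lay farthest from 1, leaving out predicted models, clones and pseudogenes, where a gene at 0 counts in one library was ranked by its bound against the floor of 3 counts. It also took up to 4 members of each list by the same order or by abundance, all measured sex-linked list members, and the usual readouts of pressure overload (Nppa, Nppb, Myh6, Myh7, Acta1, Col1a1, Col3a1, Postn, Ccn2, Tgfb1 and Atp2a2). A few genes that the rule takes are not reported here. The lists, the size rule, the naming rule and most alternatives were fixed before the data were examined.

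The size rule was tested on simulated data for the comparison of TAC with dioscin over TAC, with counts drawn for all 55401 genes. Without any difference beyond counting error, 29 genes passed as higher and 35 as lower among 15361 genes at or above 1 CPM. With an assumed coefficient of variation between mice of 0.2 and no other difference, 242 passed as higher and 269 as lower among 15340. With an assumed coefficient of 0.4, 1930 and 1952 passed among 15467. Of 200 genes changed 3-fold, 96.5% were recovered with counting error alone and 89.5% with the assumed coefficient of 0.2. For 4-fold the shares were 96% and 93%, and for 1.5-fold, below the size rule, 3.5% and 12%. Of 100 unshifted lists of 20 genes simulated with the assumed coefficient of 0.2, 5 lay apart, and of 100 lists shifted 1.5-fold, 100 did. These genes were drawn independently of each other, so the shares do not hold for lists of genes regulated together.

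Alternatives covered the scaling (DESeq2 1.42.0 size factors, total counts, upper quartile, and TMM without mitochondrially encoded genes), the filter (none, or 5 CPM), the ratio (1.5, 3, or the whole interval beyond 2), intervals widened by an assumed coefficient of variation of 0.2 or 0.4, a pseudocount of 5, and the deeper library thinned to the depth of the other. For the lists they also covered the mean in place of the median, random lists not matched, and shared members left out. Subtraction of a trend on GC content and transcript length, a restriction to protein-coding genes, and random lists from protein-coding genes were chosen after seeing the data. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.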

Results

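Gene expression was measured by RNA sequencing in hearts of C57BL/6 mice after transverse aortic constriction (TAC), with 1 library from TAC alone and 1 library from TAC with dioscin for 4 weeks (called the dioscin library). The TAC library held 16782741 counts in genes and the dioscin library 17612259. At least 1 read was counted for 23075 genes in the TAC library and for 22930 in the dioscin library. Mitochondrially encoded genes took 31.6% of the counts in the TAC library and 25.5% in the dioscin library.

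The comparison asks how gene expression in the pressure-loaded heart differs with dioscin. In the dioscin library, genes of fatty acid oxidation were higher (22 of 28 measured members), as were genes that respond to glucocorticoids (13 of 15). Pdk4, which blocks glucose entry into the mitochondrial oxidation pathway, was 27.5-fold higher (95% counting interval 25.7 to 29.5). Interferon response genes were lower (11 of 22), and so were markers of B cells (6 of 7). The 3 of 9 neutrophil markers that reached 1 CPM were lower, but without the filter that list lay inside the random range (percentile 2.73). Nppa, the gene of atrial natriuretic peptide, was 21.5-fold higher (21.1 to 22.0), and markers of atrial muscle, of mesothelium and of fat were higher too, with Myl7 at 2250-fold. The classical readouts Nppb, Myh6, Myh7, Acta1, Col1a1, Col3a1, Postn and Tgfb1 stayed inside a 2-fold difference, whereas Ccn2 was 12.2-fold and Atp2a2 2.36-fold higher.

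Of 15697 genes at or above 1 CPM, 1655 were higher and 1378 lower in the dioscin library by the size rule, which is 19.3% of them. Among the 13219 protein-coding genes, 1295 were higher and 961 lower. A difference beyond 8-fold was found for 218 genes higher and 85 lower. Of the 38 lists, 12 lay apart as higher and 8 as lower. An expectation of 1.9 holds only if the genes of a list vary independently. Genes regulated together do not, so the excess over 1.9 does not measure chance.

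**Figure D1:**
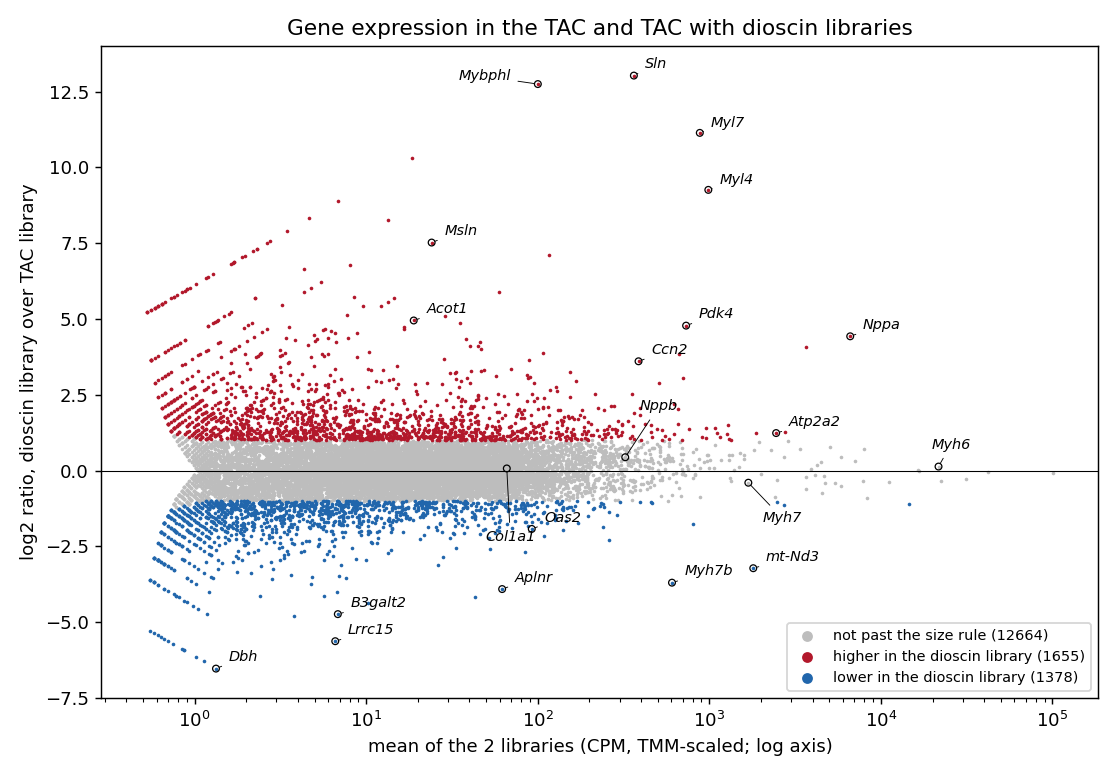
Each point is 1 gene, with the mean of the 2 libraries in TMM-scaled CPM on a log axis and the log2 ratio of the dioscin library over the TAC library. The 1655 higher genes reach a log2 ratio of 13.03 at Sln, Nppa lies at 4.43, and Myh6 lies near 0 at 0.13.

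The atrial markers differed most. Sln, which encodes sarcolipin, a regulator of the calcium pump in atrial muscle (ENSMUSG00000042045.6; chromosome 9, 53850164 to 53854560 on GRCm38), had 1 count in the TAC library and 12433 in the dioscin library, a ratio of 8350 (2251 to 495500). Myl7, the atrial regulatory myosin light chain (ENSMUSG00000020469.8; chromosome 11, 5896637 to 5898782), went from 13 to 30109 counts, 2250-fold higher (1366 to 4389). Myl4, the atrial essential light chain, was 613-fold higher (475.1 to 821), from 55 to 33721 counts. Mybphl, a myosin-binding protein of atrial and conduction tissue, had 0 counts in the TAC library and 3427 in the dioscin library, at least 936.7-fold higher. Of the 6 measured atrial markers, 5 were higher and 1 lower. The list's median log2 ratio was 10.20, or 9.72 with the gene at 0 counts taken at its floor bound, above all 10000 random lists.

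Mesothelial and fat cell markers moved the same way. Of 8 mesothelial markers, 7 were higher and none was lower, with a median log2 ratio of 5.70 (5.25 with genes at 0 counts at their floor bounds). Msln, mesothelin, was 184-fold higher (80.5 to 761), from 4 to 820 counts. The keratin genes Krt18 and Krt8 were at 0 counts in the TAC library and at least 63.77-fold and 42.98-fold higher, with the reservation that pseudogene copies could share their reads. All 6 measured adipocyte markers were higher, with a median of 4.68 (3.54 with genes at 0 counts at their floor bounds). Cfd, the fat-secreted complement factor adipsin, had 2 and 275 counts, a ratio of 111 (38.0 to 1151). Cidec, a lipid droplet protein, was at least 11.54-fold higher, and Car3, a carbonic anhydrase abundant in fat, was 17.6-fold higher (9.23 to 44.0). Their levels remained low, with 16.1 CPM for Cfd, 8.65 CPM for Car3 and 2.57 CPM for Cidec in the dioscin library.

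Among the cardiac stress genes, 4 of 17 were higher, 2 were lower and 11 did not pass the size rule, and the list did not lie apart (median log2 ratio 0.03). Nppa (ENSMUSG00000041616.9; chromosome 4, 148000722 to 148002079) went from 588 to 12660 CPM, the same direction as the atrial markers. An opposite-strand predicted gene covers 61.5% of the exonic length of Nppa, and reads of the pair cannot be told apart with this kit. Nppb, the B-type natriuretic peptide gene, had a ratio of 1.36 (1.31 to 1.41), and skeletal actin Acta1 had 1.54 (1.496 to 1.59). The ratio was 0.757 (0.745 to 0.770) for the slow myosin heavy chain Myh7 and 1.10 (1.09 to 1.10) for the adult form Myh6. Fhl1, a LIM protein of the stretch response, was 3.56-fold higher (3.30 to 3.84). Ankrd23, a titin-associated ankyrin repeat protein, was 2.90-fold lower (2.24 to 3.82).

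Of 18 adult sarcomere genes, 4 were higher and 1 was lower. Myom2, an M-band protein, was 2.15-fold higher (2.1 to 2.20), and the titin cap Tcap was 2.07-fold higher (2.03 to 2.11). Mybpc3, cardiac myosin-binding protein C, was 2.20-fold lower (2.17 to 2.23). Among 20 genes of calcium handling and ion channels, 1 was higher and 1 was lower. Atp2a2, the calcium pump SERCA2 (ENSMUSG00000029467.15; chromosome 5, 122453513 to 122502225), was 2.36-fold higher (2.32 to 2.39). Neither list lay apart (medians 0.40 and 0.02).

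Fatty acid oxidation and nuclear-encoded oxidative phosphorylation genes lay apart as higher. The median log2 ratio of the fatty acid oxidation list was 1.37, above all 10000 random lists, with 6 members not past the size rule and none lower, in the library that also held the atrial, mesothelial and fat markers (medians 10.20, 5.70 and 4.68). Besides Pdk4 (ENSMUSG00000019577.6; chromosome 6, 5483351 to 5496309), Acot1, a cytosolic acyl-CoA thioesterase, was 30.9-fold higher (20.3 to 52.2), with the reservation that its near-identical paralog could share reads with it. Of 28 nuclear-encoded genes of oxidative phosphorylation, 8 were higher and none lower (median 0.74, percentile 99.9), but their mean lay inside the random range at percentile 97.35. Sdha, Ndufb8 and Atp5a1, subunits of complexes II, I and V, were 2.47-fold (2.37 to 2.58), 2.47-fold (2.34 to 2.61) and 2.38-fold (2.32 to 2.43) higher.

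The mitochondrially encoded mRNAs had 1 of 13 members lower and none higher, and their median of -0.27 stayed inside the random range at percentile 2.94. They lay apart as lower under 4 of 9 alternatives, which were the mean (0.31), the 5 CPM filter (2.08), the GC and length correction (0.23) and random lists from protein-coding genes (2.40). The lower member was mt-Nd3, a complex I subunit, 9.32-fold lower (9.08 to 9.57). The most abundant member, mt-Co1, had a ratio of 0.953 (0.951 to 0.955). Glucose uptake and glycolysis genes did not lie apart (median 0.41), except against unmatched random lists (percentile 98.1), and 4 of 20 were higher. Pgk1, Pdha1 and Tpi1 were 2.77-fold (2.57 to 3.003), 2.17-fold (2.07 to 2.27) and 2.12-fold (2.01 to 2.25) higher. Cholesterol synthesis and uptake genes lay apart as lower (median -0.53, percentile 0.56), with 3 of 19 past the size rule, but their mean lay inside the random range at percentile 2.70. Mvd, mevalonate decarboxylase, was 2.097-fold lower (1.52 to 2.95).

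The glucocorticoid-responsive list had a median log2 ratio of 2.14, above all random lists, with no member lower, again in the library with the higher atrial, mesothelial and fat markers. Mt2, a metal-binding metallothionein, was 10.2-fold higher (8.92 to 11.9), and an opposite-strand predicted gene covers 73.5% of its exonic length. Lcn2, a secreted iron-scavenging protein that also belongs to the inflammatory list, was 13.6-fold higher (8.05 to 27.0), and Pdk4 belongs here as well. The clock gene Per1, which glucocorticoids also induce, was 2.66-fold higher (2.41 to 2.93). In the circadian clock list 3 of 15 genes were higher and 2 lower, with a median of 0.19 and a mean of -0.05, and the list did not lie apart. It pools genes of opposite phase, whose shifts can cancel, so its median cannot show whether the clock differed. Per2 was 2.33-fold higher (2.05 to 2.65) and the clock output gene Dbp 2.92-fold lower (2.33 to 3.72). Of 18 immediate early genes, 3 were higher and 4 lower, also not apart (median -0.11). Egr3 and Egr1 were 6.97-fold (4.72 to 11.03) and 3.95-fold (3.55 to 4.42) lower, whereas Nr4a3 was 5.14-fold higher (3.53 to 7.92).

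**Figure D2:**
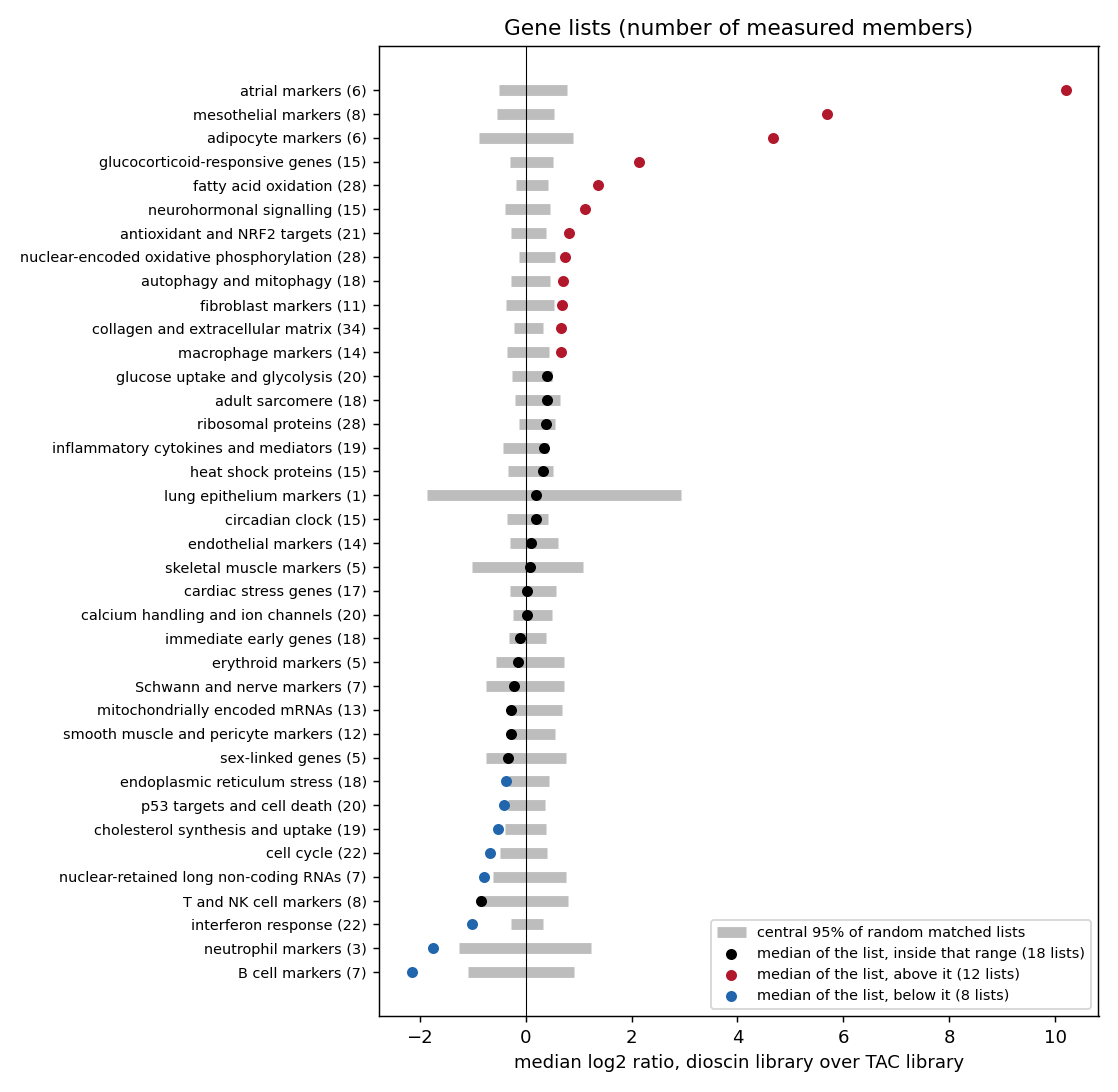
Each row is a gene list with its number of measured members, a dot for the median log2 ratio of the dioscin library over the TAC library, and a grey bar for the central 95% of 10000 random lists matched on expression. Dots of 12 lists lie above their bars and dots of 8 lists below, from 10.20 for atrial markers to -2.14 for B cell markers.

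Collagen and extracellular matrix genes lay apart as higher, with 12 of 34 higher and 1 lower (median 0.67, above all random lists), in the same library as the atrial, mesothelial and fat markers. The collagen genes Col1a1 and Col3a1 did not pass the size rule. Col1a1 had a ratio of 1.05 (0.966 to 1.14), which turns to a log2 ratio of -0.01 when libraries are scaled by total counts, and Col3a1 had 0.797 (0.762 to 0.834). The myofibroblast matrix gene Postn had 0.927 (0.857 to 1.00) and the growth factor gene Tgfb1 0.906 (0.792 to 1.03). Ccn2, connective tissue growth factor (ENSMUSG00000019997.11; chromosome 10, 24595442 to 24598683), was 12.2-fold higher (11.4 to 12.99), and an opposite-strand predicted gene covers 23.2% of its exonic length. Fmod, fibromodulin of tendon-like matrix, was 43.4-fold higher (22.3 to 116) and Comp, cartilage oligomeric matrix protein, 8.15-fold (6.19 to 11.1). Fibroblast markers were higher in 5 of 11 cases and lower in none (median 0.69, percentile 99.5). Dpep1, Scara5 and Gsn were 5.25-fold (4.79 to 5.77), 3.90-fold (3.29 to 4.66) and 2.85-fold (2.79 to 2.92) higher.

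Neurohormonal signalling genes were higher in 9 of 15 cases and lower in 1 (median 1.11, above all random lists). Npr3, the natriuretic peptide clearance receptor, was 14.9-fold higher (13.03 to 17.1). Agt, the precursor of angiotensin, was 7.18-fold higher (4.79 to 11.6), and Rgs2, a brake on G protein signalling, 5.08-fold (4.38 to 5.95). These differences too stand beside the atrial and mesothelial markers of the same library.

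Interferon response genes had a median log2 ratio of -1.01, below all 10000 random lists, with none of the 22 higher. Oas2, a sensor of viral RNA (ENSMUSG00000032690.16; chromosome 5, 120730333 to 120749853), was 3.80-fold lower (3.49 to 4.15), the interferon signalling factor Stat2 2.65-fold (2.47 to 2.85) and the guanylate-binding protein Gbp3 2.63-fold (2.41 to 2.87). The inflammatory cytokines and mediators went both ways, with 7 of 19 higher and 2 lower, and did not lie apart (median 0.34). With the 5 CPM filter they lay apart as higher (median 1.19, percentile 100), and after the GC and length correction, chosen after seeing the data, their median was -0.02. Lgals3, galectin-3, was 8.17-fold higher (6.81 to 9.95), and the adhesion molecule Vcam1 was 3.44-fold higher (3.02 to 3.96).

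B cell markers had a median of -2.14 (percentile 0.02). The B cell kinase Blk was 4.73-fold lower (3.37 to 6.93), the immunoglobulin light chain Igkc 3.52-fold lower (2.74 to 4.62), and Pax5, the B lineage factor, had 19 and 1 counts, a ratio of 12.9 in favour of the TAC library (2.99 to 782). Neutrophil markers had a median of -1.75 (percentile 0.425), and the other 6 of 9 listed genes were below 1 CPM. Without the low-count filter the list lay inside the random range (median -0.92, percentile 2.73). S100a9, S100a8 and the growth factor receptor Csf3r were 4.30-fold (2.73 to 7.29), 3.21-fold (1.70 to 6.92) and 3.36-fold (2.48 to 4.66) lower. T and NK cell markers did not lie apart (median -0.84, percentile 3.17), except against unmatched random lists (0.25), with 3 of 8 lower. Cd8a was 2.59-fold lower (1.78 to 3.90), Cd3d 3.11-fold (1.35 to 8.99) and Gzma 2.15-fold (1.26 to 3.91). Macrophage markers lay apart as higher (median 0.66, percentile 99.8), with 3 of 14 higher and 2 lower, but their mean lay inside the random range at percentile 95.3. The resident macrophage genes Lyve1 and Cd163 were 9.67-fold (8.10 to 11.7) and 3.83-fold (3.33 to 4.42) higher, whereas Ccr2, the receptor of recruited monocytes, was 4.01-fold lower (3.10 to 5.32). Erythroid markers did not lie apart (median -0.15), with 1 of 5 lower. Hbb-bs had a ratio of 0.901 (0.856 to 0.947), and Hba-a2 was 3.01-fold lower (2.51 to 3.65), with the reservation that globin copies could share reads.

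**Figure D3:**
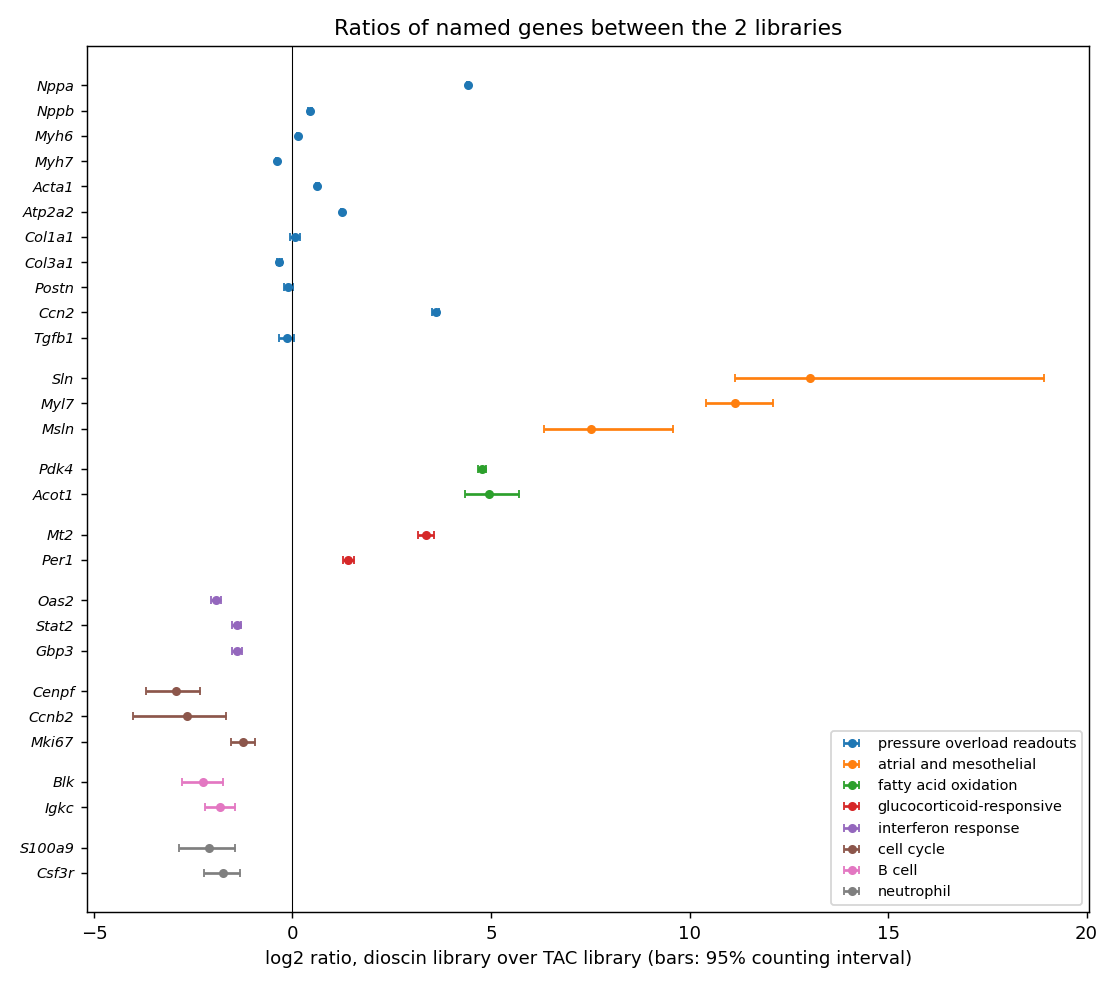
Each dot is the log2 ratio of a named gene, dioscin library over TAC library, with a bar for the 95% counting interval and colours for gene groups. Nppa (4.43) and Ccn2 (3.61) stand apart from the other readouts of pressure overload, and the interferon, cell cycle, B cell and neutrophil genes lie below 0.

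Antioxidant and NRF2 target genes lay apart as higher, with 8 of 21 higher and none lower (median 0.82, above all random lists). This list and the autophagy list also moved with the atrial, mesothelial and fat markers. Gpx3, the extracellular glutathione peroxidase, was 8.32-fold higher (7.99 to 8.67). The glutathione transferase Gsta4 was 3.74-fold higher (3.29 to 4.27) and catalase, Cat, 3.33-fold (3.05 to 3.65). Autophagy and mitophagy genes were higher in 8 of 18 cases and lower in none (median 0.71, percentile 99.95). Bnip3, a mitophagy receptor, was 7.82-fold higher (7.21 to 8.50), Gabarapl1, an autophagosome protein, 4.14-fold (3.82 to 4.50), and the cargo receptor Sqstm1 2.87-fold (2.74 to 2.99). Opposite-strand predicted genes cover 22.3% of the exonic length of Bnip3 and 28.3% of that of Gabarapl1.

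The list of p53 targets and cell death genes held members of both directions, 5 of 20 higher and 3 lower. Its median of -0.41 lay apart as lower (percentile 0.91) while its mean was 0.01, at percentile 42.9, so the direction of the list rests on the choice of the median. With the 5 CPM filter the median was -0.11, at percentile 22.0. The cell cycle inhibitor Cdkn1a was 6.10-fold higher (5.61 to 6.65), the anti-apoptotic Bcl2l1 4.27-fold (3.78 to 4.85) and the stress sensor Sesn1 2.17-fold (2.03 to 2.32). Endoplasmic reticulum stress genes lay apart as lower (median -0.38, percentile 0.83), with 1 of 18 higher and 2 lower, but their mean was inside the random range at percentile 8.81. Herpud1, which acts in protein degradation at the reticulum, was 2.87-fold higher (2.66 to 3.09). The stress factor Ddit3 was 2.28-fold lower (2.03 to 2.57) and the chaperone cofactor Sdf2l1 2.05-fold lower (1.47 to 2.92). Heat shock proteins did not lie apart (median 0.33), with 1 of 15 higher. That gene was Hspa1a at 2.30-fold (1.65 to 3.28), with the reservation that a near-identical copy could share its reads, and the abundant Hspa8 had a ratio of 1.28 (1.26 to 1.31). Cell cycle genes were lower in 7 of 22 cases and higher in none (median -0.67, percentile 0.23). Markers of B cells were lower in the same library too (median -2.14), whereas macrophage markers had a median of 0.66. Cenpf, Ccnb2 and the proliferation marker Mki67 were 7.69-fold (5.02 to 12.8), 6.36-fold (3.17 to 16.3) and 2.36-fold (1.92 to 2.92) lower.

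Endothelial markers did not lie apart (median 0.10), with 2 of 14 higher and 1 lower. Vwf, von Willebrand factor, and Pecam1 were 3.27-fold (3.08 to 3.48) and 2.19-fold (2.11 to 2.28) higher, and Egfl7 was 2.75-fold lower (2.63 to 2.88). Smooth muscle and pericyte markers stayed inside the random range at percentile 3.96 (median -0.28), although their mean lay apart as lower (2.18), with 1 of 12 higher and 3 lower. Cspg4, Notch3 and Smtn were 3.01-fold (2.65 to 3.44), 2.49-fold (2.23 to 2.79) and 2.02-fold (1.92 to 2.14) lower. Schwann and nerve markers did not lie apart (median -0.22), with Mbp 3.99-fold higher (2.96 to 5.54) as the 1 member of 7 past the rule. Cnp had a ratio of 1.05 (0.926 to 1.19), which turns to a log2 ratio of -0.01 under scaling by total counts. Of 5 measured skeletal muscle markers, 2 were higher and 1 lower, with a median of 0.08 and a mean of -0.27. Atp2a1 and Tnni2 were 4.29-fold (2.70 to 7.40) and 2.77-fold (1.84 to 4.37) higher, the first with an overlapping opposite-strand gene, and Pvalb had 40 and 1 counts, a ratio of 26.8 in favour of the TAC library (6.72 to 1605). Ager was the 1 lung epithelium marker measured, with a ratio of 1.15 (0.772 to 1.73).

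None of the 28 ribosomal protein genes passed the size rule (median 0.39, percentile 83.3, or 98.95 against unmatched random lists), and Rpl4 and Rps24 had ratios of 1.74 (1.69 to 1.79) and 1.33 (1.29 to 1.36), with the reservation that their pseudogenes could share reads. The nuclear-retained long non-coding RNAs lay apart as lower (median -0.79, percentile 0.735), with 3 of 7 lower and 1 higher, but their mean lay inside the random range at percentile 4.46. Kcnq1ot1, an antisense transcript of an imprinted region, was 3.12-fold lower (2.56 to 3.83), with the reservation that reads of both strands cannot be told apart, and Rian and Mirg of the imprinted Meg3 region were 2.77-fold (2.36 to 3.28) and 3.85-fold (2.08 to 8.20) lower. Among the sex-linked genes, the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty had 1332, 2447, 416 and 361 counts in the TAC library and 1497, 1902, 369 and 285 in the dioscin library. Xist, which is expressed from the inactive X chromosome of females, had 23 and 9 counts. That list did not lie apart (median -0.33).

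Other genes among the 12 most firmly higher were Fgf12, a modulator of sodium channels (at least 172.6-fold), Dkk3, a secreted protein of the Dickkopf family (139-fold, 98.0 to 214), and Slc26a3, an anion exchanger (at least 31.77-fold). Here and below, firmly refers to the naming order, which covers counting error alone and places genes at 0 counts by their floor bounds. By interval limits, Slc26a3 would stand below Cfd (38.04), and Cd22, Klra10 and Ighg1 below mt-Nd3 (9.076). Fgf12 had 0 and 633 counts and Dkk3 28 and 3938, the same direction as the atrial markers. Mlana, a melanocyte protein, had 1 and 458 counts, a ratio of 308 (82.5 to 18290). Scd4, a heart-expressed fatty acid desaturase with close paralogs, was 58.7-fold higher (42.4 to 86.2).

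Among the 12 most firmly lower, Aplnr, the receptor of the peptide apelin (ENSMUSG00000044338.9; chromosome 2, 85136225 to 85139923), was 15.0-fold lower (12.6 to 18.1), and Myh7b, a slow myosin heavy chain, 12.97-fold (12.3 to 13.7). Lrrc15, a surface protein of activated fibroblasts, was 49.5-fold lower (21.4 to 205.5). Dbh, which makes noradrenaline, and the collagenase Mmp13 were at 0 counts in the dioscin library and at least 11.87-fold and 9.992-fold lower. The glycosyltransferase genes Mgat5b and B3galt2 were 28.1-fold (11.99 to 117) and 26.6-fold (14.1 to 66.2) lower, and the muscle gene Ky 20.5-fold (12.8 to 37.3). Prdm1, the regulator of plasma cell maturation, was 17.5-fold lower (9.75 to 38.9). The B cell receptor partner Cd22 and the immunoglobulin heavy chain Ighg1, which resembles other heavy chain genes, were at 0 counts in the dioscin library and at least 7.576-fold and 7.307-fold lower. Klra10, an NK receptor gene of a multigene family, was at least 7.576-fold lower, with the reservation that its relatives could share reads with it.

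With 1 library per group, none of these differences has a replicate check. Simulated libraries without any treatment, but with an assumed coefficient of variation of 0.4 between mice, gave 1930 genes as higher and 1952 as lower, more than the observed counts. With an assumed coefficient of 0.2 they gave 242 and 269, fewer than observed. The spread between mice was not measured, so which value applies here is not known.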

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

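The comparison of fat genes with Pdk4, the median of the ventricular stress genes and the read density of antisense genes are tests chosen after the result was seen. Reads outside genes were the largest class of uniquely aligned reads, at 52.06% in the TAC library and 50.16% in the dioscin library, and stood out because they enter no comparison. A candidate explanation is that reads which do not mark strand were counted by strand, which leaves about as many reads on the opposite strand as in the gene. In 152 annotated antisense genes lying for at least 50% of their exonic length under an abundant coding gene, the median read density was 0.955 times that of the coding gene (quartiles 0.286 and 2.16), as this explanation needs. Ratios of genes without a partner on the other strand would keep their value, but counts of antisense genes then hold reads of their partners. No biological explanation was tested.

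Atrial and mesothelial markers were higher in the dioscin library. A general return of stress genes in ventricular muscle would need a median log2 ratio of 1 for Nppb, Myh7, Acta1, Ankrd1 and Xirp2. The median was 0.318, with a bootstrap interval over the 5 genes of -1.02 to 0.624. That interval only spans their lowest and highest value, so it could not reach 1. These 5 genes, chosen after the result was seen, argue against a return of these genes only. In the stress list, fixed beforehand, the median was 0.03, with 4 of 17 higher, among them Nppa and Fhl1 at 3.56-fold, and 2 lower. That list holds these 5 genes too, so it is not a separate check. Atrial tissue present in the dioscin library and nearly absent from the TAC library may account for the pattern, since 5 atrial-enriched genes outside the list (Nr2f2, Kcnk3, Gja5, Tbx5 and Cacna1d) had a median log2 ratio of 1.16 at percentile 99.73 of random lists. Their ratios ran from 0.855 for Cacna1d to 9.31 for Tbx5, and ventricle and vessels express some of them too. In the atrial list itself, 5 of the 6 measured members were higher in the dioscin library, but 1 was lower. Under this hypothesis Nppa would reflect the tissue taken, and an effect of dioscin on atrial genes stays open, as untested.

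The fatty acid oxidation list (22 of 28 genes past the size rule) and the glucocorticoid-responsive list (13 of 15) lay apart as higher, and the interferon list (11 of 22) and the B cell list (6 of 7) as lower. A trend on GC content and transcript length as the whole cause is argued against, since after its subtraction 4 of the 4 lists still lay apart in the same direction. This correction was chosen after seeing the data. The trend itself was small, with median log2 ratios of 0.148 and -0.0774 in the shortest and longest deciles, and -0.027 and -0.15 in the lowest and highest GC deciles. Fat tissue is argued against as the source of Pdk4, since Adipoq, Cfd, Plin1, Cidec and Lep summed to 22.0 CPM in the dioscin library, 1.62% of the 1362 CPM by which Pdk4 was higher. This comparison covers Pdk4 alone and does not decide for less abundant members, such as Acot1 at 36.7 CPM in the dioscin library. A different time of day at collection cannot be told apart from the treatment, because the clock genes of opposite phase differed by -1.02 on the log2 scale, between the values set for a shift (beyond 2) and for none (under 1). Dioscin, a difference in the tissue taken, and the feeding or stress state of the mouse may each underlie the pattern. Other differences between these hearts or between their libraries may do so too. All of these stay open, as untested.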

How the results depend on the processing

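The GC and length correction and both protein-coding restrictions were chosen after seeing the data. The count of higher genes was 1655 and of lower genes 1378. The counts became 1045 and 695 with the 5 CPM filter, 3187 and 2815 at a ratio of 1.5, 781 and 554 at a ratio of 3, 918 and 568 with the whole interval beyond 2, and 712 and 452 with an assumed coefficient of variation of 0.4. All of these follow from how strict the rule is. The other alternatives, scaling included, stayed within 1.5-fold of both counts. The higher share was 54.6% with TMM and 47.1% with total counts. No scaling moved the log2 ratios by more than 0.0822, and of 132 named genes only Col1a1 and Cnp changed sign, under total counts.

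Of the 38 lists, 25 kept their class, apart or inside the random range, under all 9 alternatives that gave a value. No list that lay apart moved to the other side of the middle of the random lists. A list inside the range could still change sign and count as kept. The circadian clock list did so, from a median of 0.19 to -0.06 with shared members left out. With the mean in place of the median, the percentiles no longer lay apart for nuclear-encoded oxidative phosphorylation (97.35), p53 targets and cell death (42.9), endoplasmic reticulum stress (8.81), cholesterol synthesis (2.70), nuclear-retained RNAs (4.46) and macrophage markers (95.3), but did for mitochondrially encoded mRNAs (0.31) and smooth muscle markers (2.18). With the 5 CPM filter, p53 targets moved inside (22.0), while inflammatory mediators (100) and mitochondrially encoded mRNAs (2.08) moved outside. Without a filter, neutrophil markers moved inside (2.73). With unmatched random lists, glycolysis (98.1), ribosomal proteins (98.95) and T and NK cell markers (0.25) lay apart. Mitochondrially encoded mRNAs lay apart after the GC and length correction (0.23) and against protein-coding lists (2.40). For the lists the cause was not tested. With 1 library per group, no library could be left out, and depth limits the fold of a gene at 0 counts to a bound. No paired analysis was possible because each group has 1 library.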

Other observations

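The genes of the atrial and clock tests were set before their values were seen, and the other values in this part were chosen after they were seen. The mitochondrial ribosomal RNAs took 1.46% of gene counts in the dioscin library against 3.16% in the TAC library. Among them, mt-Rnr2 was 2.14-fold lower (2.13 to 2.15), and mt-Rnr1, at 1.87-fold below the TAC library (1.85 to 1.88), did not pass the size rule. Mitochondrially encoded mRNAs took 23.8% and 28.0% of gene counts in the dioscin library and the TAC library. Tbx5, a transcription factor of atria and left ventricle, was 9.31-fold higher (7.67 to 11.5), Gja5, a connexin of atrial and conduction tissue, 2.32-fold (1.95 to 2.79), and Nr2f2, an atrial identity factor, 2.24-fold (1.97 to 2.55), while the channel genes Kcnk3 and Cacna1d had ratios of 1.57 (1.47 to 1.68) and 0.855 (0.606 to 1.20). In the clock test, the genes set against Arntl, Npas2 and Clock went both ways, and of them only Hlf passed the size rule. Nr1d1, Nr1d2, Ciart and Per3 were 1.90-fold (1.68 to 2.16), 1.92-fold (1.78 to 2.08), 1.995-fold (1.34 to 3.04) and 1.64-fold (1.42 to 1.91) below the TAC library. Hlf was 2.14-fold higher (1.65 to 2.82), and Tef had a ratio of 1.27 (1.19 to 1.36). The actin-binding Xirp2 was 2.03-fold lower (1.962 to 2.11).

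Long intergenic non-coding RNAs were more often lower than higher in the dioscin library (87 against 57 of 364 measured), and processed pseudogenes more often higher than lower (112 against 36 of 490). Of 775 antisense genes, 109 were higher and 113 lower. In 129 overlapping pairs of a measured antisense and an abundant coding gene, the log2 ratios had a Spearman correlation of 0.63 across pairs, which are not independent replicates. The opposite-strand partner of Nppa, Gm13054, was 16.8-fold higher (16.4 to 17.2), close to the 21.5-fold of Nppa. The log2 ratio across genes had a Spearman correlation of -0.10 with transcript length and -0.05 with GC content, and the shortest decile of genes had a median of 0.15 and the longest a median of -0.08.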
